A study of Mus musculus with 12 samples.

How the data were processed

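Levels of RNA were measured by sequencing in 12 libraries of mouse cells. Per the labels' protocols, mouse embryonic fibroblasts were grown in DMEM with 10% FBS at 37°C and 5% CO2 and treated for 24 h. Total RNA was isolated with a column kit and libraries were prepared with the NEBNext Ultra RNA kit, whose name does not state strand marking. The libraries were grouped by the treatment label into DMSO and the 3 compounds, with 3 libraries each, numbered as in the titles. Doses were 250 nM for Torin1, 10 nM for RapaLink-1 and 20 ng/ml for rapamycin.

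The deposited values were whole-number read counts per gene that the authors made with featureCounts, per the file headers, with 1 table per library, and they were used without change. Trimmomatic 0.36, STAR 2.5.2b, Subread 1.5.2, DESeq2 and the build GRCm38 are named in the submitters' processing notes. RNA selection, read length, the strand setting, the treatment of reads that match several places and the annotation release are not given in the sources used here, so overlapping or antisense genes and close copies may share reads, and such genes are given as uncertain. The tables held 49315 genes, 19906 of them without any count. Symbols came from GENCODE M21, a GRCm38 annotation that held 49056 of the IDs, and 91.4% of these had the same start and end in the count tables. Another 259 IDs had no entry, and 73 symbols stood on several IDs. Gene positions are those of the count tables. Total counts were 30075870 to 39423703 per library, and mitochondrially encoded messages took 1.08% to 1.39% of them.

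Genes were tested with edgeR 4.0.16 in R 4.3.3, limma 3.58.1 being used for list tests and voom. Genes with too few counts were removed with filterByExpr by group, which left 15917, and libraries were scaled with TMM factors. All 12 libraries entered a robust quasi-likelihood fit with the group as its only term, which gave 8 residual degrees of freedom and a median prior of 154. Each of the 6 pairs of groups was a contrast, tested on both sides and adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. All adjusted p-values of genes come from this test. Log2 fold changes are given with their standard errors and CPM with the SD over 3 libraries, and log-CPM used a prior count of 2. With 3 libraries against 3, an exact permutation test of a single value cannot go below 0.1.

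Before the data were examined, 44 gene lists were written down, covering metabolism, translation, the cell cycle, matrix, contraction, immune response, stress, lysosomes, signalling and markers of cell types. All 1029 listed symbols were matched, 3 of them by a synonym. Lists with at least 5 tested members, 40 in all, were compared with the other genes by camera with a preset correlation of 0.01 and again with a correlation estimated per list, with adjustment over the 40 lists of a comparison. Members were counted by the adjustment over all genes and again adjusted over the list alone.

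The rule for naming genes was fixed at the same time. In each comparison it takes called genes with a mean of at least 10 CPM, no overlap between the 6 libraries and a symbol that is not provisional, the 8 with the largest rise and the 8 with the largest fall. It adds up to 4 members with the smallest p of each list described and a set of genes of the mTOR pathway against DMSO (Mtor, Rptor, Rictor, Fkbp1a, Fkbp5, Irs2, Pdgfrb and Ccnd1). Last, within the same limits, are the 5 rises and 5 falls shared by all 3 compounds whose smallest change was largest. The text may name fewer, from the top of each order, and 1 gene the rule takes is not reported here. Members of lists with too few tested genes are named where only 1 was tested, and Eef1a1 was named because it had the most counts.

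Shared calls against the same DMSO libraries were set beside simulated unchanged groups and beside the overlap of independent lists. In the simulations all 12 libraries, DMSO included, were drawn from the DMSO means. Replicate pairs of a group were compared by a chi-square test over genes with at least 20 counts, and chi-square over its degrees of freedom was 1.33 to 1.99, so no pair looked like a library deposited more than once. Exonic overlap with other genes was computed from the exon intervals in the count tables.

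The test was checked on simulated counts drawn from the real means and library sizes with 200 genes changed, 50 at each fold. At folds of 1.2, 1.5, 2 and 4 it recovered 29, 33, 46 and 48 for rapamycin against DMSO (15640 genes), 36, 38, 47 and 50 for Torin1 against DMSO (15645 genes), and 38, 37, 43 and 46 for RapaLink-1 against DMSO (15626 genes). It recovered 32, 39, 41 and 47 for Torin1 against rapamycin (15640 genes), 29, 37, 45 and 47 for RapaLink-1 against rapamycin (15638 genes) and 30, 41, 43 and 48 for RapaLink-1 against Torin1 (15633 genes). In the same order, 21, 8, 12, 13, 10 and 16 unchanged genes were called. A list of 51 genes shifted by 0.3 was recovered at a median of 0.29 to 0.30, and 0 other lists were called. Genes were drawn independently there, so the check does not cover false calls of lists whose genes vary together. Since only the 200 genes and this list were changed, it does not cover scaling when most genes change either.

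The alternatives were DESeq2 1.42.0, limma-voom, DESeq2's size factors and TMM factors without mitochondrially encoded genes and the 50 genes with the highest mean. Others were no filter on low counts, a filter at a mean of 5 CPM, a fit to the 6 libraries compared and a minimum absolute log2 fold change of 1. Further ones were a trend with gene length removed (loess span 0.3), the replicate number as a block, both of these together, the estimated list correlation, and leaving out each library in turn. Upper-quartile scaling was added after the data were seen. Camera was repeated with the estimated correlation, upper-quartile scaling, DESeq2's size factors and no filter on low counts. It was also repeated with the replicate block, with the gene length trend removed and without each library. The other alternatives were run for genes only. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.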

Results

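RNA levels were measured by sequencing in mouse embryonic fibroblasts (MEFs), connective tissue cells cultured from mouse embryos, after 24 h with inhibitors of the kinase mTOR. Rapamycin, a macrolide that binds FKBP12 and with it mTOR complex 1, was given at 20 ng/ml. Torin1, a compound that competes with ATP at the mTOR kinase, was given at 250 nM, and RapaLink-1, in which rapamycin is joined by a linker to an mTOR kinase inhibitor, at 10 nM. Control cells received the solvent DMSO. The doses differ between the compounds, so each comparison between compounds is one between these doses. Each of the 4 groups held 3 libraries, 12 in all. Total counts were 34696405 to 39423703 for DMSO, 30495065 to 38809352 for rapamycin, 31328365 to 37762480 for Torin1 and 30075870 to 36206209 for RapaLink-1. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. That spread was small, with a biological coefficient of variation of 1.48%.

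The 4 groups lay apart on the first pair of principal components of log2 CPM, which held 66.8% and 8.1% of the variance. On the first component the DMSO libraries lay between -55.8 and -54.6 and the rapamycin libraries between -19.7 and -18.8, while RapaLink-1 lay between 33.4 and 33.6 and Torin1 between 40.4 and 41.8. Messages for cytosolic ribosomal proteins made up 4.94% to 4.99% of the counts with DMSO, 5.15% to 5.32% with rapamycin, 6.93% to 7.08% with Torin1 and 6.75% to 6.77% with RapaLink-1. Eef1a1, which encodes translation elongation factor eEF1A1, was the gene with the most counts in each of the 12 libraries, at 0.921% to 1.71% of the total. Among the 4 groups, 13582 of the 15917 genes tested differed.

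**Figure D1:**
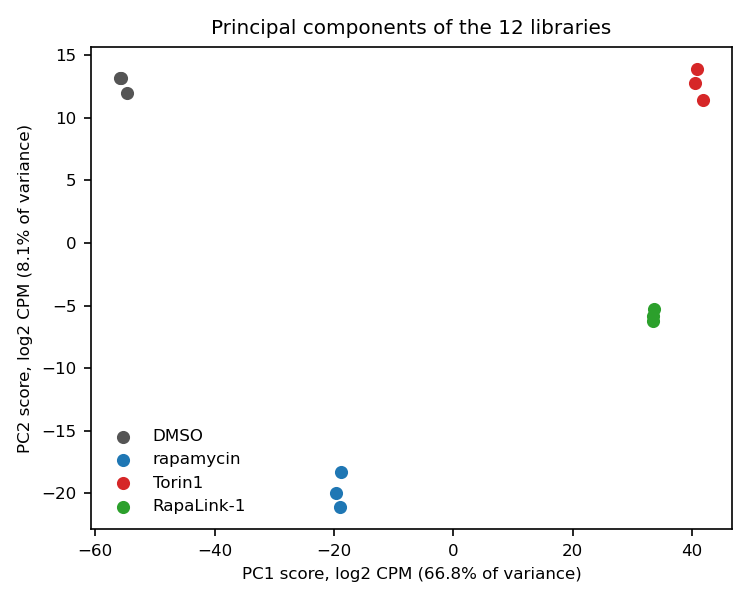
Scores of the 12 libraries on the first and second principal components of log2 CPM, one point per library, with the share of variance on each axis. The rapamycin libraries lie between the DMSO libraries and those of Torin1 and RapaLink-1 on the first component.

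The comparison of rapamycin with DMSO asked which messages changed under partial inhibition of mTOR. Rapamycin lowered messages for ribosome assembly, amino acid supply, nucleotide synthesis, fatty acid synthesis, glycolysis, DNA replication and the proteasome, and raised messages for inflammatory cytokines, matrix proteases, lysosomal proteins and YAP/TEAD targets. Of 15917 genes tested, 4381 rose and 5127 fell, 484 and 84 of them by at least 2-fold. With upper-quartile scaling, chosen after the data were seen, 5481 rose and 4061 fell. Log2 fold changes over all genes tested ran from -3.4 to 5.14. The largest rises and falls named here and in each comparison below are those within the limits of the naming rule, such as its minimum mean CPM. On the log2 scale (± standard error) the largest rises were in Anxa8, a calcium-binding annexin, at 2.46 ± 0.09, and Lcn2, a secreted carrier of iron-binding siderophores, at 1.83 ± 0.04. They were followed by the chemokine precursor Ppbp at 1.76 ± 0.05, the ubiquitin ligase Fbxo32 (atrogin-1) at 1.75 ± 0.06 and the collagenase Mmp13 at 1.70 ± 0.11. The largest falls were in the mitochondrial folate enzyme Aldh1l2 at -1.68 ± 0.05 and the mTORC1 inhibitor Ddit4 (REDD1) at -1.52 ± 0.05. Next came the semaphorin Sema5a at -1.42 ± 0.07, the uracil-DNA glycosylase Ung at -1.17 ± 0.06 and the tubulin Tuba4a at -1.07 ± 0.05. Tuba4a is uncertain, because 37.3% of its exonic bases overlap the antisense gene Stk16.

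Biosynthetic groups fell with rapamycin. All 40 ribosome biogenesis genes fell, with a median of -0.54 (camera adjusted p = 1.79e-20), among them nucleolin (Ncl, -0.72 ± 0.01) and the rRNA transcription factor partner Mybbp1a (-0.68 ± 0.02). ATF4 targets, which supply serine, glycine and other amino acids, fell in 26 of 27 cases, with 1 rise when adjusted over the list alone and a median of -0.70 (adjusted p = 1.49e-11). The serine synthesis enzyme Psat1 was at -0.91 ± 0.02 and the leucine transporter Slc7a5 at -0.95 ± 0.02. Falls were also called for 19 of 20 cytosolic aminoacyl-tRNA synthetases (median -0.45) and 17 of 18 genes of purine and pyrimidine synthesis (median -0.47, with Cad at -0.64 ± 0.02). All 31 proteasome subunits (median -0.45, with Psmd2 at -0.55 ± 0.02) and 29 of 36 translation factors (median -0.32) fell as well. In these 4 lists 1, 1, 0 and 7 members rose. Among lipid genes, all 16 of fatty acid synthesis fell (median -0.34), with the desaturase Scd2 at -0.50 ± 0.01 and fatty acid synthase (Fasn) at -0.45 ± 0.02. In cholesterol synthesis and uptake 20 of 25 fell and 1 rose, 2 when adjusted over the list alone, with a median of -0.21. That call was lost with an estimated correlation (adjusted p = 0.0514). Glycolysis fell in 16 of 19 genes (median -0.54), with lactate dehydrogenase (Ldha) at -0.77 ± 0.02, and Gapdh, whose reads may be shared with its many pseudogenes and whose value is therefore uncertain, at -0.74 ± 0.01. The pentose phosphate pathway fell in 6 of 7 genes (median -0.31, adjusted p = 0.103 with an estimated correlation).

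Proliferation and stress groups fell as well. All 40 DNA replication genes fell (median -0.36), with the helicase subunit Mcm5 at -0.63 ± 0.02, and 27 of 34 mitosis genes fell while 2 rose, 3 adjusted over the list alone (median -0.19), with the checkpoint kinase Bub1b at -0.40 ± 0.02. ER chaperones and other genes of the unfolded protein response fell in 17 of 20 cases (median -0.28), with Hsp90b1 at -0.51 ± 0.01 and Hspa5 (BiP) at -0.51 ± 0.01. NRF2 targets fell in 14 of 16 cases (median -0.42), with the glutathione transferase Gsta4 at -0.96 ± 0.03. The nuclear-encoded respiratory chain fell in 37 of 49 cases (median -0.17, adjusted p = 0.15 with an estimated correlation).

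Rising groups were led by inflammatory cytokines and NF-kB targets, of which 19 of 23 rose (median 0.70, adjusted p = 1.43e-09), with Lcn2 as above and the chemokine Ccl2 at 0.74 ± 0.02. Complement genes rose in 5 of 9 cases (median 0.61), with C1s1 at 1.16 ± 0.02, uncertain because of a near-identical copy and an antisense gene, and C3, the central complement protein, at 0.88 ± 0.02. Matrix proteases and their inhibitors rose in 14 of 18 cases (median 0.35), with Timp2 at 0.56 ± 0.01 and Adamts5 at 0.75 ± 0.02. YAP/TEAD targets rose in 11 of 19 cases (median 0.24), with Ccn2 (CTGF, uncertain because 23.2% of its exonic bases overlap an antisense gene) at 1.36 ± 0.02 and Ccn1 (CYR61) at 0.79 ± 0.02. Lysosomal proteins rose in 37 of 51 cases (median 0.16), with prosaposin (Psap) at 0.34 ± 0.01, and autophagy and TFEB/TFE3 genes in 21 of 39 (median 0.12), with Calcoco1 at 1.04 ± 0.04. Immediate early genes rose in 16 of 25 cases (median 0.24), with Junb at 0.56 ± 0.02. The call for FoxO targets and receptor feedback (17 of 30 rose, median 0.12, with Txnip at 1.17 ± 0.03) was lost with an estimated correlation (adjusted p = 0.15). So were those for SRF and contractile genes (12 of 20, median 0.12, with smooth muscle actin Acta2 at 0.53 ± 0.01, adjusted p = 0.15) and mitochondrially encoded messages (7 of 13, median 0.22, adjusted p = 0.15).

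The 77 cytosolic ribosomal protein genes did not move as a group with rapamycin, as 24 rose and 27 fell (28 adjusted over the list alone) around a median of -0.01 (adjusted p = 0.882). The median turned to 0.0525 with upper-quartile scaling (adjusted p = 0.0416, with 0.0416 to 0.976 over the alternatives). Single ribosomal protein genes, such as Rpl7a at -0.30 ± 0.01 and Rps20 at 0.28 ± 0.02, may share reads with pseudogenes and are uncertain. Lists that did not pass were fatty acid oxidation (median -0.06), other HIF targets (-0.06), mTOR pathway components (-0.07), G1 cyclins and CDK inhibitors (-0.01), p53 targets (-0.13), collagens and structural matrix (0.01), interferon response (0.11), SR splicing factors (-0.08) and the circadian clock (-0.13). Of these, fatty acid oxidation, other HIF targets and G1 cyclins changed sign with upper-quartile scaling. Among the genes of mTOR signalling chosen beforehand, Mtor was at 0.15 ± 0.03, Rictor at 0.22 ± 0.03, Irs2 at 0.35 ± 0.02, Ccnd1 at 0.12 ± 0.02, Rptor at -0.20 ± 0.03 and Fkbp5 at -0.25 ± 0.03. Fkbp1a (-0.09 ± 0.02) and Pdgfrb (-0.06 ± 0.02) also passed, but both calls were lost with upper-quartile scaling and with a filter at a mean of 5 CPM, at -0.03 with either for Fkbp1a and at 0.00 with either for Pdgfrb. Of the 52 genes named for this comparison, markers and shared genes included, 51 passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at adjusted p-values of at most 0.00101. In these 51 the 3 rapamycin and 3 DMSO libraries did not overlap. The naming rule asks this of the largest changes, here and in the other comparisons, so the 10% that chance gives in unselected genes is no benchmark. Lack of overlap was also common among all 15917 genes tested. It held for 63%, 78.5% and 77.6% of them with rapamycin, Torin1 and RapaLink-1 against DMSO. Against rapamycin it held for 69.2% with Torin1 and 67.4% with RapaLink-1, and for RapaLink-1 against Torin1 for 42.2%. Camera adjusted p-values of the 26 lists past the test ran from 1.79e-20 to 0.0168, and those of the 19 that held with an estimated correlation from 0.00176 to 0.046. For lists described as changed, in this and the other comparisons, the counts given were the same when adjusted over the list alone unless another is given. In all 26 lists that passed, the mean log-CPM of the members separated the 3 rapamycin from the 3 DMSO libraries. Here and in the other comparisons these lists were chosen by a test on the same libraries, so separation is no further support.

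Torin1 was compared with DMSO to find the messages that changed when the kinase itself was inhibited. Torin1 lowered messages for DNA replication, mitosis, cholesterol synthesis, amino acid supply, ER chaperones and the proteasome, with list medians between -1.36 and -0.94 on the log2 scale, and raised messages for contractile proteins, complement, cytokines and lysosomal proteins. Of the 15917 genes, 6332 rose and 6090 fell, 1921 and 1011 of them by at least 2-fold. With upper-quartile scaling, which moved the median of all genes by 0.12, 7640 rose and 4999 fell. After Anxa8 at 3.99 ± 0.07, the largest rises were in the lipid droplet protein Plin4 at 3.66 ± 0.09, Ppbp at 3.25 ± 0.05, Mmp13 at 3.23 ± 0.09 and Fbxo32 at 3.15 ± 0.05. The largest falls were in Aldh1l2 at -4.51 ± 0.07, the mitochondrial folate enzyme Mthfd2 at -3.23 ± 0.04 and Ddit4 at -3.16 ± 0.06, then Ung at -2.86 ± 0.07 and Psat1 at -2.61 ± 0.02.

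Cell cycle genes fell together, with all 40 DNA replication genes lower at a median of -1.33 (camera adjusted p = 1.69e-16) and all 34 mitosis genes lower at a median of -1.36 (adjusted p = 3.41e-16). The ribonucleotide reductase subunit Rrm2 was at -1.98 ± 0.02, the histone and DNA methylation reader Uhrf1 at -1.85 ± 0.02, cyclin A2 (Ccna2) at -1.58 ± 0.02 and topoisomerase Top2a at -1.08 ± 0.02. Every one of the 25 genes of cholesterol synthesis and uptake fell (median -1.14), with Hmgcs1 at -1.16 ± 0.02. The 16 genes of fatty acid synthesis all fell (median -0.91), with Scd2 at -2.01 ± 0.02. ATF4 targets fell in 26 of 27 cases (median -1.30), with Psat1 as above and Slc7a5 at -2.06 ± 0.02. Aminoacyl-tRNA synthetases fell in 19 of 20 cases (median -0.73), with Aars at -1.77 ± 0.02. All 31 proteasome subunits fell (median -0.95, with Psmd1 at -1.34 ± 0.02). So did 19 of 20 genes of the unfolded protein response (median -0.94), with calreticulin (Calr) at -1.64 ± 0.01 and Hspa5 at -1.62 ± 0.02. Median falls were also called for NRF2 targets (14 of 16, median -0.74), purine and pyrimidine synthesis (15 of 18, median -0.72) and ribosome biogenesis (36 of 40, median -0.60, with the nucleolar protein Nolc1 at -1.18 ± 0.02). Calls for glycolysis (13 of 19 fell, median -0.66, adjusted p = 0.15) and the pentose phosphate pathway (6 of 7, median -0.70, adjusted p = 0.109) were lost with an estimated correlation. So were those for translation factors (25 of 36, median -0.34, adjusted p = 0.321) and the respiratory chain (41 of 49, median -0.33, adjusted p = 0.15). Translation factors also lost their call with the gene length trend removed (adjusted p = 0.0521, with 0.00269 to 0.321 over the alternatives).

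Ribosomal protein messages rose with Torin1 in 73 of 77 cases and fell in 3, with a median of 0.47, though the list's call was lost with an estimated correlation (adjusted p = 0.195). Single members are uncertain, since pseudogenes may share their reads. SRF and contractile genes rose in 18 of 20 cases (median 0.72), with Acta2 at 1.76 ± 0.01 and the myosin light chain Myl9 at 1.48 ± 0.02. Complement rose in 6 of 9 cases (median 1.68), with C3 at 1.93 ± 0.02 and C1s1 at 2.86 ± 0.02. Cytokines and NF-kB targets rose in 18 of 23 cases (median 0.73), with cyclooxygenase 2 (Ptgs2) at 2.17 ± 0.02 and the NF-kB inhibitor Tnfaip3 at 2.04 ± 0.03. Lysosomal proteins rose in 41 of 51 cases (median 0.48), with the cholesterol carrier Npc2 at 1.25 ± 0.02, and autophagy genes in 24 of 39 (median 0.36), with Calcoco1 at 1.95 ± 0.03. YAP/TEAD targets rose in 16 of 19 cases (median 0.42). Matrix proteases rose in 13 of 18 (median 0.31), with Timp3, uncertain because 21.3% of its exonic bases overlap an antisense gene, at 1.12 ± 0.02. FoxO targets rose in 20 of 30 cases (median 0.34, with Txnip at 2.05 ± 0.03, adjusted p = 0.109 with an estimated correlation). Mitochondrially encoded messages rose in 7 of 13 (median 0.37, adjusted p = 0.268 with an estimated correlation). The interferon response (median 0.38) did not pass (adjusted p = 0.0581). It passed without Torin1 replicate 2 (adjusted p = 0.048, with 0.035 to 0.107 over the alternatives). Without a call were also fatty acid oxidation (0.03), other HIF targets (0.04), mTOR pathway components (median -0.13), SR splicing factors (-0.20), immediate early genes (0.24), p53 targets (-0.36), G1 cyclins (-0.31), the circadian clock (-0.04) and collagens (-0.06). The last 2 medians changed sign with upper-quartile scaling. Of the genes chosen beforehand, Rictor was at 0.69 ± 0.02, Irs2 at 1.28 ± 0.02, Mtor at 0.23 ± 0.03, Rptor at -0.51 ± 0.03, Fkbp1a at -0.38 ± 0.02, Fkbp5 at -1.42 ± 0.03 and Ccnd1 at -0.79 ± 0.02. Ccnd1 is uncertain in each comparison, as 23.4% of its exonic bases overlap an antisense gene. Pdgfrb, at 0.04 ± 0.02, lost its call without DMSO replicate 1 (0.03) or 2 (0.03) and without Torin1 replicate 1 (0.04), 2 (0.04) or 3 (0.02). The same held, at 0.02 each, with DESeq2, with its size factors, with no filter on low counts and with the gene length trend removed. All 46 genes named for Torin1 against DMSO passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at adjusted p-values of at most 0.0315, with no overlap between the 3 and 3 libraries. In camera, the 25 lists past the test had adjusted p-values of 1.69e-16 to 0.0334, and those of the 18 that held with an estimated correlation from 0.00157 to 0.0325. The members' mean log-CPM separated the 3 Torin1 from the 3 DMSO libraries in all 25 lists that passed.

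RapaLink-1 was compared with DMSO in the same way. It lowered messages for cholesterol synthesis, DNA replication, mitosis, amino acid supply, ER chaperones and the proteasome and raised messages for complement, cytokines, lysosomal proteins, YAP/TEAD targets and the interferon response. Against DMSO, 6165 genes rose and 6036 fell, 1672 and 919 of them by at least 2-fold. With upper-quartile scaling, which moved the median of all genes by 0.13, 7629 rose and 4823 fell. The largest rises were in Anxa8 at 3.96 ± 0.07, Plin4 at 3.82 ± 0.09, Mmp13 at 3.31 ± 0.09, Fbxo32 at 3.17 ± 0.05 and C1s1 at 2.70 ± 0.02. The largest falls were in Aldh1l2 at -4.19 ± 0.07, Mthfd2 at -3.20 ± 0.04, Ung at -3.16 ± 0.07, Ddit4 at -2.95 ± 0.06 and the leucine-rich repeat protein Lrrc17 at -2.72 ± 0.05.

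All 25 genes of cholesterol synthesis and uptake fell with RapaLink-1 (median -1.30, camera adjusted p = 3.75e-12), with Hmgcs1 at -1.31 ± 0.02. The 40 DNA replication genes (median -1.22, with Mcm5 at -1.70 ± 0.02) and the 34 mitosis genes (median -1.06, with Ccna2 at -1.34 ± 0.02) all fell. The 31 proteasome subunits (median -0.98, with Psmd1 at -1.31 ± 0.02) and the 16 genes of fatty acid synthesis (median -0.89, with Scd2 at -1.90 ± 0.02) likewise all fell. So did 26 of 27 ATF4 targets (median -1.29) and 18 of 20 genes of the unfolded protein response (median -0.88, with Calr at -1.63 ± 0.01). Falls were also called for 19 of 20 aminoacyl-tRNA synthetases (median -0.77), 14 of 16 NRF2 targets (median -0.65), 37 of 40 ribosome biogenesis genes (median -0.65) and 15 of 18 genes of nucleotide synthesis (median -0.64). Calls for glycolysis (14 of 19 fell, median -0.72, adjusted p = 0.146) and the pentose phosphate pathway (6 of 7, median -0.84, adjusted p = 0.0808) were lost with an estimated correlation. The same was true of translation factors (25 of 36, median -0.37, adjusted p = 0.255), the respiratory chain (44 of 49, median -0.40, adjusted p = 0.0855) and G1 cyclins and CDK inhibitors (9 of 15, median -0.24, adjusted p = 0.0769). The G1 list, with cyclin D2 (Ccnd2) at -0.99 ± 0.02, also lost its call with upper-quartile scaling (adjusted p = 0.0505, with 0.00267 to 0.0769 over the alternatives).

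Rises with RapaLink-1 were called for 45 of 51 lysosomal genes (median 0.53), with Npc2 at 0.93 ± 0.02 and the protease Ctsa at 0.94 ± 0.02. Of 39 autophagy genes 24 rose (median 0.31), with Calcoco1 at 1.90 ± 0.03. Cytokines and NF-kB targets rose in 20 of 23 cases (median 0.89, with Ptgs2 at 1.75 ± 0.02) and complement in 7 of 9 (median 1.06, with C3 at 2.36 ± 0.02). YAP/TEAD targets rose in 16 of 19 cases (median 0.46, with Ccn2 at 1.78 ± 0.02) and SRF and contractile genes in 16 of 20 (median 0.51, with Acta2 at 1.04 ± 0.01). Matrix proteases rose in 13 of 18 cases (median 0.31) and the interferon response in 15 of 23 (median 0.58, with the MHC class I light chain B2m at 0.58 ± 0.02). Ribosomal protein genes rose in 71 of 77 cases and fell in 5 (median 0.38), a call lost with an estimated correlation (adjusted p = 0.21). FoxO targets rose in 18 of 30 cases (median 0.26, with Txnip at 2.31 ± 0.03). This call was lost with an estimated correlation (adjusted p = 0.21) and without RapaLink-1 replicate 2 (adjusted p = 0.0571, with 0.0159 to 0.21 over the alternatives). Lists without a call were mitochondrially encoded messages (median 0.13), immediate early genes (0.10), collagens (-0.28), SR splicing factors (-0.21) and p53 targets (-0.28). Neither was one made, with medians that changed sign under upper-quartile scaling, for fatty acid oxidation (-0.01), mTOR pathway components (-0.12) and the circadian clock (-0.06). Other HIF targets (0.00), also without a call, changed sign with DESeq2's size factors. Of the genes chosen beforehand, Rictor was at 0.52 ± 0.03, Irs2 at 1.11 ± 0.02, Mtor at 0.18 ± 0.03, Rptor at -0.43 ± 0.03, Fkbp1a at -0.48 ± 0.02, Fkbp5 at -1.16 ± 0.03 and Ccnd1 at -0.67 ± 0.02. Pdgfrb, at -0.09 ± 0.02, turned to 0.04 with upper-quartile scaling, past the test in that direction, and lost its call with a filter at a mean of 5 CPM (-0.01). The 40 genes named for RapaLink-1 against DMSO passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at adjusted p-values of at most 0.0415. In 39 of them, all but Alas2, the 3 and 3 libraries did not overlap. For the 27 lists past the camera test the adjusted p-values lay between 4.7e-16 and 0.0402, and those of the 20 that held with an estimated correlation from 0.00168 to 0.043. Each of the 27 lists that passed separated the 3 RapaLink-1 from the 3 DMSO libraries by the mean log-CPM of its members.

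**Figure D2:**
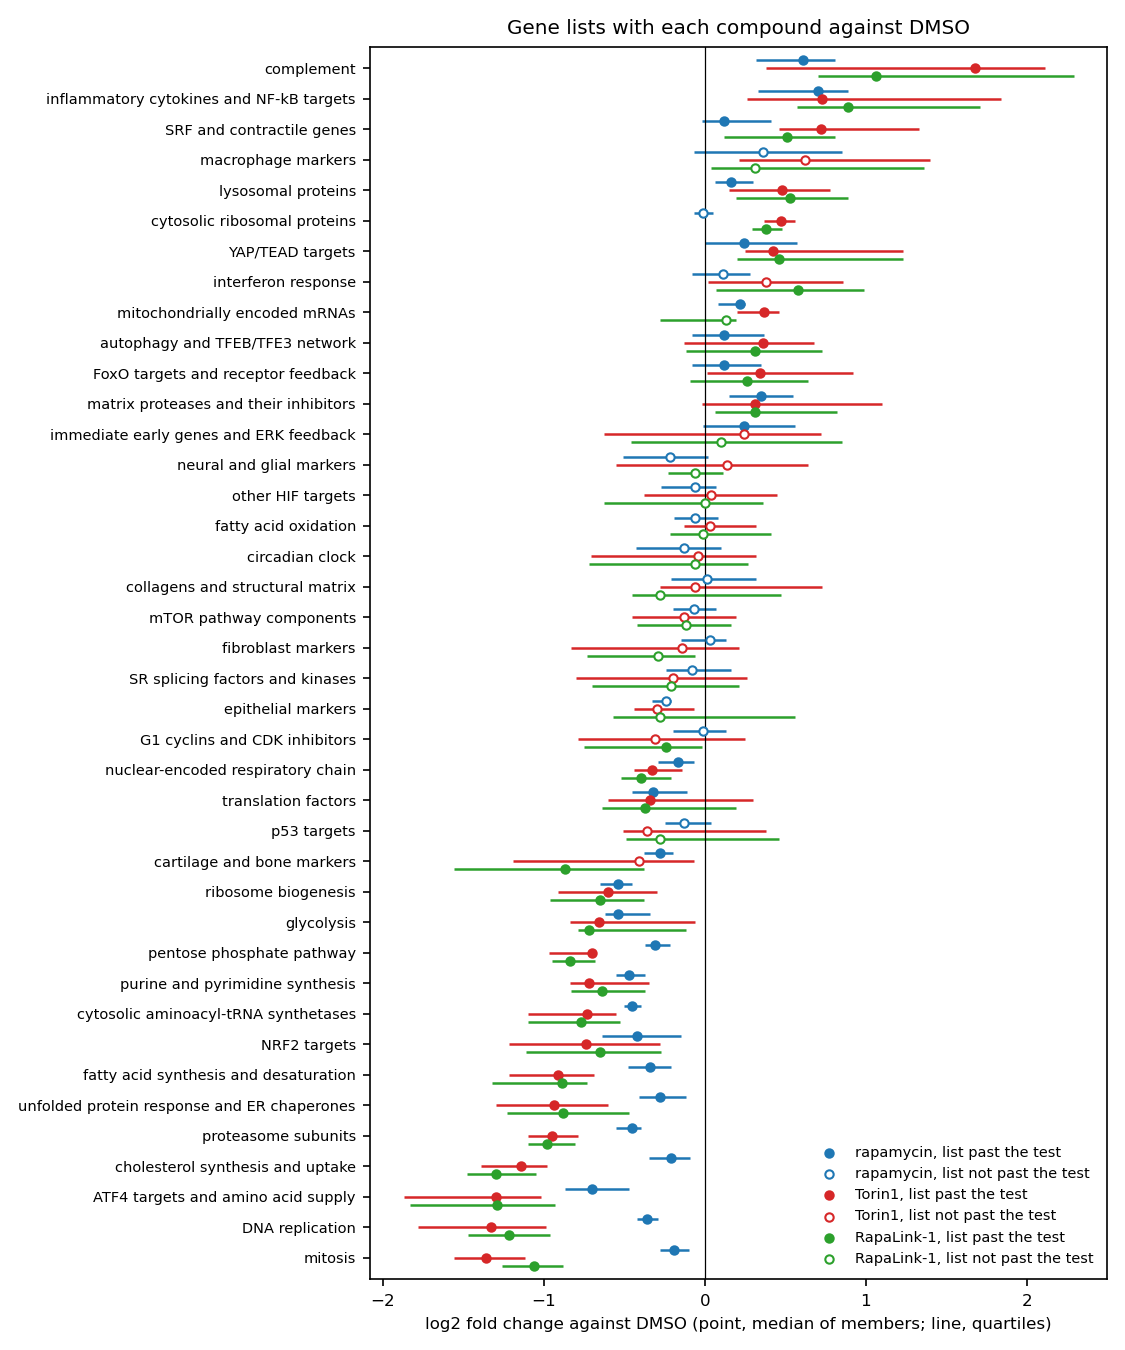
Median log2 fold change of each gene list against DMSO for rapamycin, Torin1 and RapaLink-1, one point per list and compound. DNA replication has medians of -0.36, -1.33 and -1.22, and cytosolic ribosomal proteins of -0.01, 0.47 and 0.38, the first of which changes sign with upper-quartile scaling.

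Genes that changed the same way with more than one compound were counted next. Rapamycin and Torin1 shared 3601 rises and 4228 falls, with 768 genes called in opposite directions. Rapamycin and RapaLink-1 shared 3577 and 4257, with 696 opposite, and Torin1 and RapaLink-1 shared 5481 and 5499, with 166 opposite. With upper-quartile scaling rapamycin, Torin1 and RapaLink-1 lowered 4061, 4999 and 4823 genes in all. For each pair the smaller of these totals lies under the shared falls given here, so the division into rises and falls depends on the scaling. Independent lists of the same sizes would share 1743 and 1962, 1697 and 1944, and 2453 and 2309 genes. In simulations, all 12 libraries, the DMSO ones included, were drawn from the DMSO means. The unchanged groups there shared at most 0.1 genes per direction on average over 20 simulations. The simulated spread was that between these libraries, which may be technical, so a deviation of the real DMSO cultures is not part of it. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.751, 0.775 and 0.927, against 0.496, 0.491 and 0.489 in the simulations. Their covariances of 0.274, 0.266 and 0.598 exceeded the simulated ones of 0.0215, 0.0213 and 0.0215 by 0.253, 0.245 and 0.577. With 3 DMSO libraries the controls could not be split, and part of the excess of shared calls may come from the shared controls.

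All 3 compounds raised 3383 genes and lowered 4052. Where rapamycin and Torin1 moved a gene the same way, the change with rapamycin was smaller in 85.5% of genes, with a median ratio of 0.538. Against RapaLink-1 it was smaller in 84.3%, with a median ratio of 0.56. Within the limits of the naming rule, the shared rise whose smallest change was largest was in Anxa8 (ENSMUSG00000021950, GRCm38 chromosome 14, 34085981 to 34100571). It was followed by Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252) and Ppbp (ENSMUSG00000029372, chromosome 5, 90768518 to 90770063). Next in that order were Fbxo32 (ENSMUSG00000022358, chromosome 15, 58175879 to 58214892) and Mmp13 (ENSMUSG00000050578, chromosome 9, 7272514 to 7283331). Anxa8 stood at 2.21 ± 0.06 CPM with DMSO (SD, n = 3), 12.2 ± 0.43 with rapamycin, 35.2 ± 1.46 with Torin1 and 34.5 ± 0.99 with RapaLink-1. Lcn2 stood at 17.2 ± 0.85, 61.2 ± 2.04, 103.9 ± 3.33 and 100.8 ± 2.12 CPM. The corresponding falls were in Aldh1l2 (ENSMUSG00000020256, chromosome 10, 83487450 to 83534140) and Ddit4 (ENSMUSG00000020108, chromosome 10, 59949675 to 59951770), followed by Ung (ENSMUSG00000029591, chromosome 5, 114130386 to 114139323), the phosphatase Dusp9 (ENSMUSG00000031383, chromosome X, 73639419 to 73643514) and the imprinted, retrotransposon-derived Peg10 (ENSMUSG00000092035, chromosome 6, 4747306 to 4760517). Aldh1l2 stood at 42.7 ± 0.75 CPM with DMSO, 13.4 ± 0.66 with rapamycin, 1.86 ± 0.12 with Torin1 and 2.34 ± 0.04 with RapaLink-1. Ddit4 stood at 41.0 ± 0.88, 14.3 ± 0.26, 4.58 ± 0.23 and 5.28 ± 0.20 CPM (SD, n = 3 each). Of the exonic bases of Aldh1l2, 14.1% overlap an antisense gene, so its level is uncertain.

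**Figure D3:**
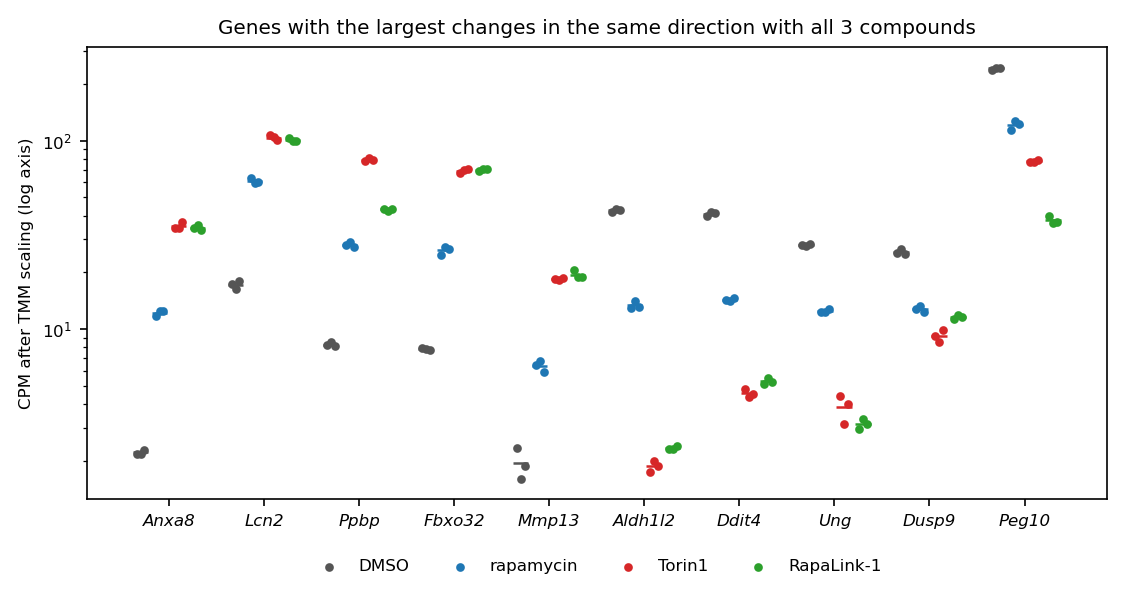
CPM of the 10 genes that changed most in the same direction with all 3 compounds, within the limits of the naming rule. Points are libraries on a log axis, by group. The DMSO libraries lie below those of each compound for Anxa8, Lcn2, Ppbp, Fbxo32 and Mmp13 and above them for Aldh1l2, Ddit4, Ung, Dusp9 and Peg10.

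Torin1 was next set against rapamycin directly, at 250 nM and 20 ng/ml. Cell cycle, cholesterol, fatty acid, amino acid and ER chaperone messages were lower with Torin1 than with rapamycin, and contractile, complement and lysosomal messages were higher. Of the 15917 genes, 5451 were higher and 5288 lower with Torin1, 772 and 523 of them by at least 2-fold. With upper-quartile scaling 6359 were higher and 4489 lower. The largest rises were in Plin4 at 2.83 ± 0.08, the noncoding RNA Zfas1 at 2.45 ± 0.03, the chemokine Ccl5 at 2.10 ± 0.05, the IGF-binding protein Igfbp2 at 2.09 ± 0.06 and the collagen Col27a1 at 2.09 ± 0.04. Zfas1 is uncertain, since 18.5% of its exonic bases overlap other genes, among them snoRNA genes and the antisense Znfx1. The largest falls were in Aldh1l2 at -2.83 ± 0.09, Mthfd2 at -2.34 ± 0.04, cyclin E1 (Ccne1) at -2.06 ± 0.06, thymidine kinase (Tk1) at -1.98 ± 0.03 and the ER protein Sdf2l1 at -1.90 ± 0.07.

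Ribosomal protein genes were higher with Torin1 than with rapamycin in 76 of 77 cases (median 0.48, camera adjusted p = 1.08e-24), with Rpl10a at 0.98 ± 0.02 and Rpl3 at 0.82 ± 0.01. The call was lost with an estimated correlation (adjusted p = 0.145). SRF and contractile genes rose in all 20 cases (median 0.65), with Acta2 at 1.23 ± 0.01 and Myl9 at 1.09 ± 0.02. Complement rose in 7 of 9 cases (median 0.97, with C1s1 at 1.71 ± 0.02 and C3 at 1.05 ± 0.02). Lysosomal proteins rose in 38 of 51 (median 0.33, with Npc2 at 0.85 ± 0.02). Mitosis fell in all 34 cases (median -1.13, adjusted p = 1.35e-20), with Top2a at -0.97 ± 0.02 and Ccna2 at -1.26 ± 0.02. DNA replication fell in all 40 (median -0.98), with Rrm2 at -1.68 ± 0.02. Lower in every member were also cholesterol synthesis and uptake (25 genes, median -0.84) and fatty acid synthesis (16 genes, median -0.63). ATF4 targets were lower in 25 of 27 cases (median -0.72, with Psat1 at -1.71 ± 0.02) and the unfolded protein response in 18 of 20 (19 adjusted over the list alone, median -0.65, with Calr at -1.23 ± 0.01). Calls lost with an estimated correlation were those for YAP/TEAD targets (13 of 19 higher, median 0.24, adjusted p = 0.0524), FoxO targets (20 of 30, median 0.17, adjusted p = 0.141) and cytokines (15 of 23, median 0.38, adjusted p = 0.2). Of lists that were lower, the same applied to proteasome subunits (29 of 31 lower, median -0.48, adjusted p = 0.0516), aminoacyl-tRNA synthetases (15 of 20, median -0.26, adjusted p = 0.126) and NRF2 targets (12 of 16, median -0.41, adjusted p = 0.0952). It applied as well to the pentose phosphate pathway (6 of 7, median -0.43, adjusted p = 0.131), the respiratory chain (33 of 49, median -0.11, adjusted p = 0.43) and SR splicing factors (13 of 20, median -0.18, adjusted p = 0.285). Fatty acid oxidation (median 0.12, adjusted p = 0.0574) passed without rapamycin replicate 1 (adjusted p = 0.038, with 0.023 to 0.128 over the alternatives). The 22 genes named here all passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at adjusted p-values of at most 1.67e-60, with no overlap between the 3 and 3 libraries. Camera adjusted p-values of the 19 lists past the test ran from 1.08e-24 to 0.0192, and those of the 9 that held with an estimated correlation from 0.000865 to 0.0394. The mean log-CPM of the members separated the 3 Torin1 from the 3 rapamycin libraries in all 19 lists that passed.

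RapaLink-1 and rapamycin, which share the rapamycin part and differ by the linked kinase inhibitor, were compared at 10 nM and 20 ng/ml. RapaLink-1 gave lower levels of cholesterol, cell cycle, amino acid, ER chaperone and proteasome messages and higher levels of lysosomal, complement, contractile and interferon response messages. There were 5088 genes higher and 5260 lower with RapaLink-1, 500 and 409 by at least 2-fold, and with upper-quartile scaling 6296 were higher and 4311 lower. Plin4 at 3.00 ± 0.08, Zfas1 at 2.28 ± 0.03, the lysosomal glycoprotein Gpnmb at 1.75 ± 0.04 and Col27a1 at 1.64 ± 0.04 rose most. Aldh1l2 at -2.51 ± 0.09, Mthfd2 at -2.32 ± 0.04, Ung at -1.99 ± 0.09 and Lrrc17 at -1.94 ± 0.06 fell most. Cholesterol synthesis and uptake fell in all 25 cases (median -1.01, camera adjusted p = 1.87e-15) and DNA replication in all 40 (median -0.85, with Tk1 at -1.67 ± 0.03). Mitosis fell in all 34 (median -0.89, with Ccna2 at -1.01 ± 0.02) and fatty acid synthesis in all 16 (median -0.66, with Scd2 at -1.40 ± 0.02). ATF4 targets fell in 23 of 27 cases (median -0.76, with Psat1 at -1.59 ± 0.02) and the unfolded protein response in 17 of 20 (median -0.57, with Calr at -1.21 ± 0.01). Proteasome subunits fell in 30 of 31 (median -0.47, with Psmd1 at -0.86 ± 0.02) and G1 cyclins and CDK inhibitors in 11 of 15 (median -0.33, with Ccnd1 at -0.80 ± 0.02). Lysosomal proteins rose in 40 of 51 cases (median 0.38, with the glucosidase Gaa at 0.91 ± 0.02) and SRF and contractile genes in 19 of 20 (median 0.39, with Acta2 at 0.51 ± 0.01). YAP/TEAD targets rose in 15 of 19 cases (16 adjusted over the list alone, median 0.38). The interferon response rose in 13 of 23 (median 0.53, with B2m at 0.31 ± 0.02) and complement in 6 of 9 (median 0.85, with C1s1 at 1.54 ± 0.02).

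Ribosomal protein genes were higher with RapaLink-1 than with rapamycin in 75 of 77 cases (median 0.38, camera adjusted p = 1.18e-23), with Rpl10a at 0.85 ± 0.02. This call was lost with an estimated correlation (adjusted p = 0.126). The same held for cytokines (16 of 23 higher, median 0.28, adjusted p = 0.0808) and NRF2 targets (12 of 16 lower, median -0.41, adjusted p = 0.0512). Among other lower lists it held for aminoacyl-tRNA synthetases (16 of 20, median -0.29, adjusted p = 0.0837), the pentose phosphate pathway (6 of 7, median -0.47, adjusted p = 0.0788) and the respiratory chain (35 of 49, 36 adjusted over the list alone, median -0.20, adjusted p = 0.173). It held also for SR splicing factors (14 of 20, median -0.19, adjusted p = 0.156), fibroblast markers (9 of 11, median -0.25, adjusted p = 0.0788) and cartilage and bone markers (5 of 7, median -0.48, adjusted p = 0.103). Collagens (median -0.08, adjusted p = 0.0886) passed without RapaLink-1 replicate 2 (adjusted p = 0.0431, with 0.0187 to 0.456 over the alternatives). All 20 genes named between RapaLink-1 and rapamycin passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at adjusted p-values of at most 5.76e-39, with no overlap between the 3 and 3 libraries. In camera, the 22 lists past the test had adjusted p-values of 1.18e-23 to 0.0442, and those of the 13 that held with an estimated correlation from 0.000949 to 0.027. In all 22 lists that passed, the 3 RapaLink-1 and the 3 rapamycin libraries did not overlap in the members' mean log-CPM.

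RapaLink-1 at 10 nM and Torin1 at 250 nM differed less from each other than either did from DMSO or rapamycin, by the count of genes called. Cell cycle messages were higher with RapaLink-1, and contractile messages were lower. Of the 15917 genes, 2659 were higher and 2618 lower with RapaLink-1, 53 and 173 of them by at least 2-fold. Under upper-quartile scaling 2978 were higher and 2394 lower. Over all genes tested the log2 fold changes ran from -3.35 to 2.61. Within the limits of the naming rule, the largest rises were in the transcription factor Klf2 at 0.97 ± 0.06 and the adenylate cyclase Adcy7 at 0.69 ± 0.06. Next were the lysyl oxidase relative Loxl4 at 0.68 ± 0.03 and Ildr2 at 0.67 ± 0.05. The largest falls were in proenkephalin (Penk) at -1.66 ± 0.08, Igfbp2 at -1.58 ± 0.06, Itm2a at -1.52 ± 0.04 and Prl2c2, a proliferin gene, at -1.52 ± 0.03. Prl2c2 may share reads with near-identical family members, and Penk and Ildr2 overlap antisense genes (over 14.3% of the exonic bases of Penk), so these 3 values are uncertain.

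All 34 mitosis genes were higher with RapaLink-1 than with Torin1 (median 0.26, camera adjusted p = 1.28e-23), with Top2a at 0.28 ± 0.02 and the kinesin Kif20a (33.2% overlapped by the antisense Cdc23, so uncertain) at 0.34 ± 0.02. Of 40 DNA replication genes, 25 were higher and 2 lower (26 and 2 adjusted over the list alone, median 0.13), with Rrm2 at 0.52 ± 0.02 and Uhrf1 at 0.37 ± 0.02. SRF and contractile genes were lower in 19 of 20 cases (median -0.33), with Acta2 at -0.72 ± 0.01 and Myl9 at -0.69 ± 0.02. These 3 calls held with an estimated correlation, at adjusted p-values of 0.00766, 0.00766 and 0.00843. The call for higher lysosomal proteins (33 of 51, 36 adjusted over the list alone, median 0.09, adjusted p = 0.0523) was lost with an estimated correlation. So were those for the interferon response (10 of 23, median 0.14, adjusted p = 0.055, with H2-K1 at 0.60 ± 0.03, uncertain among near-identical class I genes) and unfolded protein response (10 of 20, 11 adjusted over the list alone, median 0.08, adjusted p = 0.0705). Likewise lost were those for lower collagens and structural matrix (24 of 31, median -0.23, adjusted p = 0.0523, with periostin Postn at -1.34 ± 0.02 and Thbs1 at -0.42 ± 0.01) and cholesterol synthesis and uptake (19 of 25, 21 adjusted over the list alone, median -0.15, adjusted p = 0.0523, with Cyp51 at -0.39 ± 0.02). This was also so for mitochondrially encoded messages (7 of 13, 8 adjusted over the list alone, median -0.27, adjusted p = 0.0696, with mt-Cytb at -0.27 ± 0.01) and ribosomal proteins (73 of 77, 74 adjusted over the list alone, median -0.09, adjusted p = 0.344). It was so for the respiratory chain (31 of 49, 32 adjusted over the list alone, median -0.08, adjusted p = 0.213), cartilage and bone markers (5 of 7, median -0.26, adjusted p = 0.055) and FoxO targets (15 of 30, median -0.06, adjusted p = 0.195). Ribosome biogenesis (10 of 40 lower, 9 adjusted over the list alone, median -0.04, adjusted p = 0.164 with an estimated correlation) also lost its call without RapaLink-1 replicate 1 (adjusted p = 0.0885, with 0.00468 to 0.164 over the alternatives). ATF4 targets (median 0.05, adjusted p = 0.227) passed without Torin1 replicate 1 (adjusted p = 0.0451, with 0.0451 to 0.61 over the alternatives).

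Other groups did not pass between RapaLink-1 and Torin1, which does not show that the compounds acted alike on them. Their medians, with the quartiles of the members, were -0.01 (-0.03 to 0.02) for proteasome subunits, -0.03 (-0.10 to 0.03) for fatty acid synthesis, 0.02 (-0.05 to 0.08) for autophagy genes, 0.05 (-0.01 to 0.07) for glycolysis and 0.04 (-0.13 to 0.13) for YAP/TEAD targets. Among the genes shared by all 3 compounds, the difference had a 95% interval of -0.11 to 0.05 for Anxa8, -0.10 to 0.01 for Lcn2, -0.04 to 0.08 for Fbxo32 and -0.04 to 0.19 for Mmp13. It was 0.04 to 0.60 for Aldh1l2 and 0.03 to 0.40 for Ddit4. None of these 6 passed after adjustment. By contrast, Ppbp was lower with RapaLink-1 by -0.87 ± 0.03 on the log2 scale and Peg10 by -1.04 ± 0.03, while Dusp9 was higher by 0.33 ± 0.07. Ung was lower by -0.29 ± 0.11 (95% interval -0.52 to -0.07), though its 3 and 3 libraries overlapped. This call was lost without Torin1 replicate 1 (-0.19) or 3 (-0.25) and without RapaLink-1 replicate 1 (-0.25) or 3 (-0.28). It was also lost with no filter on low counts (-0.29), DESeq2 (-0.28), limma-voom (-0.28) and a fit to the 6 libraries alone (-0.29). Among the mTOR genes, Mtor had an interval of -0.11 to 0.00 and did not pass, though it did at -0.07 with the gene length trend removed. Rictor (-0.17 ± 0.02), Irs2 (-0.18 ± 0.02), Pdgfrb (-0.13 ± 0.02) and Fkbp1a (-0.09 ± 0.02) were lower with RapaLink-1. Fkbp5 (0.25 ± 0.04), Ccnd1 (0.12 ± 0.02) and Rptor (0.08 ± 0.03) were higher. The call of Rptor was lost without Torin1 replicate 2 (0.07) or RapaLink-1 replicate 2 (0.08) and with the gene length trend removed (0.06). Of the 37 genes named between RapaLink-1 and Torin1, 30 passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at adjusted p-values of at most 0.0368. In 29 of these 30, all but Ung, the 3 and 3 libraries did not overlap. The other 7 did not pass. For the 14 lists past the camera test the adjusted p-values lay between 1.28e-23 and 0.0113. In 13 of the 14 lists that passed, the members' mean log-CPM separated the 3 RapaLink-1 from the 3 Torin1 libraries, with FoxO targets as the exception.

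**Figure D4:**
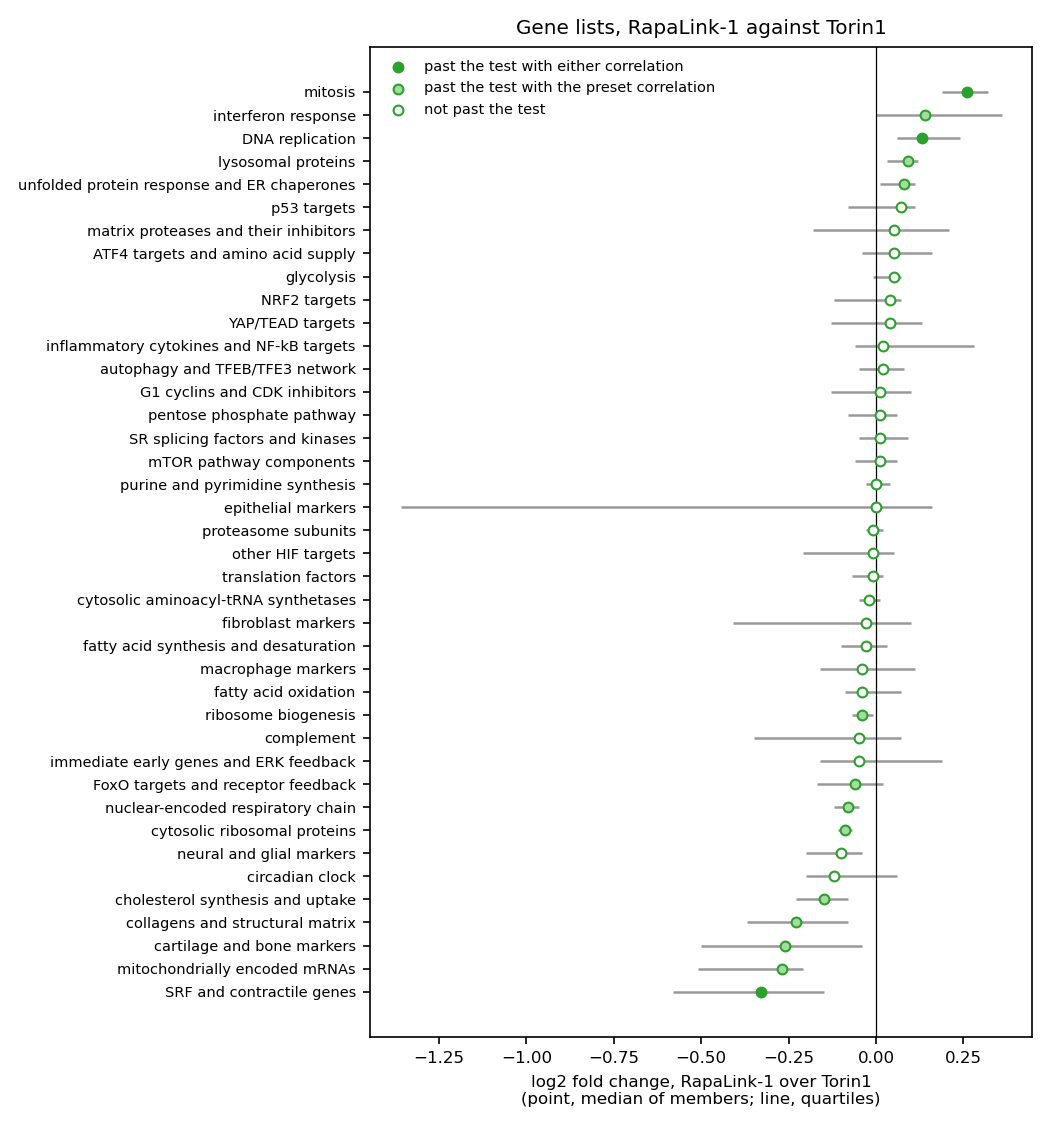
Median log2 fold change of RapaLink-1 over Torin1 for the 40 gene lists with at least 5 tested members (points) with the quartiles of the members (lines). Mitosis and DNA replication lie above 0 and SRF and contractile genes below 0 with calls that held with either correlation, while purine and pyrimidine synthesis and other HIF targets, near 0, change sign with another scaling.

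Markers of other cell types that cultures from whole embryos can hold were followed in the same libraries. Against DMSO, no call was made for macrophage markers (6 of 14 tested, medians 0.36, 0.62 and 0.31 with rapamycin, Torin1 and RapaLink-1) or epithelial markers (5 of 11, medians -0.24, -0.30 and -0.28). Nor was one made for neural and glial markers (5 of 11, medians -0.22, 0.14 and -0.06, the last of which changed sign with upper-quartile scaling). Fibroblast markers (11 of 12 tested) had medians of 0.03, -0.14 and -0.29 without a call against DMSO. Vimentin (Vim) was at -0.19 ± 0.01 with rapamycin, and Cd34 was at -1.23 ± 0.02 and S100a4, uncertain because 51.7% of its exonic bases overlap another gene, at -1.08 ± 0.02 with Torin1. Cartilage and bone markers (7 of 11 tested) fell with rapamycin in 5 cases (median -0.28, adjusted p = 0.0584 with an estimated correlation) and with RapaLink-1 in 6 (median -0.87, adjusted p = 0.0413 with an estimated correlation), with osteopontin (Spp1) at -0.28 ± 0.02 and -1.95 ± 0.02. They did not pass with Torin1 (median -0.41). Too few members for a list test were measured of the adipocyte (4 of 10, medians -0.39, -0.12 and 0.02) and endothelial markers (4 of 11, medians 0.03, -0.05 and -0.01). This was also so for skeletal muscle (4 of 12, medians 0.63, 1.24 and 0.98) and red blood cell markers (1 of 7, Alas2, at -0.23, -0.91 and -0.85). The calls of Alas2 with Torin1 and RapaLink-1 were lost without DMSO replicate 3, at -0.65 and -0.59. The first was also lost without Torin1 replicate 1 (-0.90), 2 (-0.90) or 3 (-0.95) and the second without RapaLink-1 replicate 2 (-0.70) or 3 (-0.70). Both calls were also lost with DESeq2 (-0.94 and -0.86), with no filter (-0.93 and -0.86) and with upper-quartile scaling (-0.78 and -0.71). The endothelial medians for Torin1 and RapaLink-1 changed sign and the adipocyte median for Torin1 reached 0 with upper-quartile scaling. Of 138 genes, those named with a value and the largest changes of each comparison, 47 overlap another gene in exonic bases. Of the genes named and besides those given above, Txnip (19.4%), Spp1 (18.8%), Ctsa (17.4%), Hsp90b1 (15.7%), Alas2 (15.5%), Aars (15.1%) and Ccna2 (12.5%) overlap by over 10% and are uncertain.

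In no list that passed did the median and the test differ in sign, in any of the 6 comparisons.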

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

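Upper-quartile scaling was chosen after the data were seen, and the other alternatives before. Every count of changed genes stayed within 1.5 times its value, in each comparison, under the alternatives for normalization, filter, test, gene length and samples. DESeq2 called 8232, 11594, 11318, 9614, 9119 and 4115 genes (rapamycin, Torin1 and RapaLink-1 against DMSO, Torin1 and RapaLink-1 against rapamycin, RapaLink-1 against Torin1), of which 8202, 11287, 11070, 9517, 9057 and 4081 were among the genes of the main test. A minimum absolute log2 fold change of 1, which by construction removes genes, left 568, 2932, 2591, 1295, 909 and 226 genes, 3550 among the 4 groups, and 461, 457 and 2127 genes shared by rapamycin and Torin1, rapamycin and RapaLink-1, and Torin1 and RapaLink-1.

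Without 1 library at a time the counts, in the same order, lay at 8880 to 9076, 12058 to 12147, 11774 to 11911, 10286 to 10478, 9779 to 9995 and 4660 to 4851. They lay at 13339 to 13599 among the 4 groups and at 7364 to 7448, 7375 to 7453 and 10607 to 10658 for the shared genes. The lists past the camera test numbered 26 to 26, 25 to 26, 26 to 27, 19 to 20, 22 to 23 and 13 to 15. With an estimated correlation 9 lists passed for Torin1 against rapamycin, 13 for RapaLink-1 against rapamycin and 3 for RapaLink-1 against Torin1, down from 19, 22 and 14. That setting raises the variance allowed for genes that vary together, and the cause for single lists was not tested.

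Upper-quartile scaling turned the median of the ribosomal protein list, rapamycin against DMSO, to 0.0525 (adjusted p = 0.0416) and Pdgfrb, RapaLink-1 against DMSO, to 0.0442. From -0.01 and -0.09, both moved by about the shift that this scaling gave the median of all genes, 0.062 and 0.134. The same scaling moved the share of calls that rose from 46.1% to 57.4% for rapamycin against DMSO. For Torin1 and RapaLink-1 against DMSO the share moved from 51% to 60.4% and from 50.5% to 61.3%. For Torin1 and RapaLink-1 against rapamycin it moved from 50.8% to 58.6% and from 49.2% to 59.4%. For RapaLink-1 against Torin1 it moved from 50.4% to 55.4%, to 55% with DESeq2's size factors and to 56.1% with DESeq2. List alternatives cover only the settings under which camera was repeated, which leave out DESeq2, limma-voom and the filter at a mean of 5 CPM, among others. Of 2880 list alternatives, 2795 kept the direction and side of the threshold, 56 lost the call, 51 of them with an estimated correlation, and 1 reversed. Another 28 gained a call, 16 of them with no filter on low counts. Of 4281 alternatives for the genes named, 4237 kept both, 41 lost the call, 2 gained one (Mtor, RapaLink-1 against Torin1, with the gene length trend removed) and 1 reversed. The 41 were for Pdgfrb, Fkbp1a, Alas2, Ung and Rptor.

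The replicate numbers did not pair the libraries, as the deviations of same-numbered libraries correlated at -0.039 to 0.059, 0 of 18 pairs were over 0.1, and 3 of 12 libraries correlated best with their own number. The replicate block gave 9516, 12414, 12184, 10741, 10348 and 5322 genes. It ended 1 list call, FoxO targets for RapaLink-1 against DMSO (adjusted p = 0.0507, with 0.0159 to 0.21 over the alternatives), and no other call of a list or of a gene named. At 30075870 to 39423703 counts per library, the largest standard errors among the genes named against DMSO were those of Alas2, at 0.40 with Torin1 and 0.39 with RapaLink-1, where it stood at 0.24 CPM at most.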

Other observations

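The gene families, the genes that moved in opposite directions and the imprinted genes below were chosen after their values were seen, as were the tests of overall strength and of other cell types and the matching on abundance alone. The tests of splits, gene length and abundance, pseudogenes, TOP messages, nonsense-mediated decay and depth were set before their results were seen, but the one of nonsense-mediated decay was left out after Upf1 and Smg1 had been seen and then restored. The first test of overall strength, on ratios of list medians, had 4 of 24 lists above 1.1 and 8 under 0.9, of which 0 and 2 were past the direct test with an estimated correlation. The first test of other cell types was the median change of 25 markers (0.00, with 4 rises and 4 falls). Both were replaced after these values were seen. A further version of the first, over all 3972 genes changed by both compounds and apart by the direct test, had 34.5% with the larger change with RapaLink-1 and was replaced by one on the members of the lists. For the cell types, a bound on the share of markers called one way was added after the median of 0.913 CPM for cartilage and bone markers had been seen.

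Nuclear pore genes (prefix Nup, 20 tested) had median log2 fold changes of -0.36, -0.77 and -0.79 with rapamycin, Torin1 and RapaLink-1 against DMSO, with 18 falls each. Mitochondrial ribosomal protein genes (Mrpl, 49 tested) had medians of -0.27, -0.46 and -0.51, with 43, 44 and 44 falls. Guanylate-binding protein genes (Gbp, 8 tested) rose in 6, 8 and 8 cases, at medians of 0.76, 1.43 and 1.62, and Serpina genes (8 tested) in 6, 8 and 7, at 0.50, 1.53 and 0.58. The members of these last families are close copies, so their counts are uncertain. All these medians exceeded in size the shifts that upper-quartile scaling gave the median of all genes, at 0.06, 0.12 and 0.13. Among 349 families tested by camera, none of the 4 passed with an estimated correlation (lowest adjusted p = 0.0693).

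With 550 genes, rapamycin on one side and Torin1 and RapaLink-1 on the other were called in opposite directions against DMSO, 241 higher and 309 lower with rapamycin, and in 65 the smallest of the 3 changes was over 0.25. Dkk2, a secreted Wnt antagonist, was at 0.48 with rapamycin, -0.71 with Torin1 and -1.01 with RapaLink-1. The nucleolar protein gene Npm1, whose reads may be shared with pseudogenes, and the chaperone gene Hspa8 went the other way, at -0.60, 0.47 and 0.33 and at -0.40, 0.33 and 0.36. The imprinted genes H19 and Igf2, which are neighbours on chromosome 7, moved apart, with H19 at -0.82, -0.18 and -1.21 and Igf2 at 0.35, 1.68 and 0.78. H19 stood at 124.6 ± 2.51 CPM with DMSO, 70.6 ± 3.15 with rapamycin, 109.9 ± 1.36 with Torin1 and 53.9 ± 0.78 with RapaLink-1 (SD, n = 3).

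Ribosomal protein messages were higher with Torin1 and with RapaLink-1 than with rapamycin, at medians of 0.48 and 0.38 (list calls lost with an estimated correlation, at adjusted p = 0.145 and 0.126). Protein-coding genes matched on exonic length and abundance, though less abundant (median 458 against 689 CPM), had medians of -0.18 and -0.17. Those matched on abundance alone (684 CPM) had -0.04 and -0.08. In neither kind did any of the sets reach the ribosomal protein median (0 of 1000), which argues against exonic length and abundance as the cause. Exonic length sums all annotated exons of a gene, so the length of the messages themselves was not matched and its effect stays untested. Ribosomal protein pseudogenes held with rapamycin only 5.15% and 6.54% of the CPM that the genes gained and themselves rose, by 304 and 198 CPM, which argues against reads moving from them, although all 768 tested pseudogenes, at 4114 CPM against gains of 19540 and 15380, exceed the bound of 10% set for the ribosomal ones, and rose as well. Other messages with a 5' TOP start, a sequence shared by messages of the translation machinery, rose in 18 of 18 cases. Their medians were 0.46 and 0.37 against upper bounds of 0.15 and 0.08 for matched sets. Matched sets, here and above, were drawn gene by gene, so their spread does not allow for genes that vary together. A response of TOP messages as a class is a candidate explanation, as a hypothesis. Slower nonsense-mediated decay stays open, since the median of 7 of its factors, -0.23 and -0.19, met the bound set against it but hid members that went both ways, from Upf1 at -0.62 and -0.57 to Smg6 at 0.33 and 0.34, and for that reason, seen afterwards, the median was not used to decide.

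RapaLink-1 and Torin1 differed in 14 lists, with mitosis and DNA replication higher and contractile genes lower with RapaLink-1 in calls that held with an estimated correlation. A stronger action of Torin1 at its dose is a candidate explanation for these 3 lists, as a hypothesis. Of their 77 members changed by both compounds and apart by the direct test, 3.9% changed more with RapaLink-1. That share cannot decide, since these lists were chosen for a difference opposite to their shared change against DMSO. Members apart in that direction must change more with Torin1. Of 216 such members of the other 11 lists, 105 changed more with RapaLink-1 (48.6%) and 111 with Torin1. These lists were also chosen by the direct test, so the share depends on which lists passed. Over all 3972 genes changed by both compounds and apart, it was 34.5%. One difference in overall strength would leave few members with the larger change on the weaker side. Members on both sides argue against it there. Thinning each library to 30075870 counts moved no list median by more than 0.0082, which argues against depth. The highest median over the markers of 6 other cell types was 0.154 CPM in either group, with 54 of 66 markers under 1 CPM. That of fat cell markers was at most 0.0407 CPM. These low medians argue against such cells in number (the most abundant of each type were Nes (192), Flt1 (94.2), Krt19 (17.7), Cd14 (4.53), Acta1 (2.11), Alas2 (0.24) and, for fat cells, Fabp4 (14.8)). Only 4 of 10 fat cell markers were tested, with 2 higher and 0 lower with RapaLink-1, too few for the bound on the share called one way. Cartilage and bone cells stay open, since the median of their listed markers was at most 0.913 CPM but 5 of 7 tested cartilage and bone markers were lower with RapaLink-1 and 1 higher (median -0.26, adjusted p = 0.055 with an estimated correlation), as does a difference between the compounds at these doses, untested.

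Other splits of the libraries were tested for each count. In edgeR fits to the 6 libraries compared, the real split gave 9362, 12174, 12005, 10586, 10284 and 5288 genes and the highest of the other splits 0, and 1 of 10 splits gave as many each time. The 10 splits are too few for a share under 0.05. For the difference among the 4 groups, 1 of 100 splits, the real one, gave as many as its 13582 genes, the highest of the others being 7465. At that threshold a chance assignment of these libraries to groups is excluded. Chance differences between cultures are not, since the labels do not say that the libraries of a group came from separate cultures.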
